A study of Oncorhynchus mykiss with 9 samples.

How the data were processed

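RNA was extracted with Trizol from spleens of rainbow trout, and libraries were made by standard Illumina protocols, per the labels. The 9 libraries were grouped by their labels as normoxia at 0 h, moderate hypoxia at 12 h and severe hypoxia at 12 h, with 3 libraries each. The authors deposited 1 table of genes with an expected count and an FPKM value per library. Expected counts are estimates of reads per gene that need not be whole, and as deposited they were not normalized; some of them were not whole. FPKM values are the authors' fragment counts scaled by gene length and library size. Bowtie2 2.2.8 and HISAT2 are named in the submitters' processing notes without their roles. The counting tool, the genome build and the filters are not given in the sources used here, so no coordinates are given.

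The table held 44057 genes, of which 41897 had an NCBI gene number and 2160 an MSTRG number for an assembled transcript outside the annotation. All 41897 numbers matched the gene table of the assembly USDA_OmykA_1.1, which was used for names only. A further 38 broken lines continued the text of the line before and were left out. Gene symbols came from the table for 37539 genes and rest on similarity to genes of other species, so paralogs left by the salmonid genome duplication often share a symbol and could share reads.

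The libraries held 14.6 to 20.4 megacounts in all. Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. TMM normalization, filterByExpr by group and 1 robust quasi-likelihood fit over all 9 libraries were used, and p-values were adjusted with the Benjamini-Hochberg method over the 28245 tested genes at a threshold of 0.05. Every adjusted p of a gene is from edgeR's quasi-likelihood test unless another tool is named. SE is the absolute log2 fold change divided by the square root of the F statistic of that test. It therefore rests on a spread shared by all 9 libraries and does not show differences in spread between groups. Levels are TMM-normalized CPM (counts scaled to library size). Genes with a TMM level near 0 in a group depend on few counts, since 1 CPM before TMM scaling stands for 14.6 to 20.4 counts. The TMM factors were 0.905 to 1.15.

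Before the values were seen, 30 gene lists, the comparisons, the alternatives and the rule for named genes were fixed. The lists were hypoxia response, glycolysis, oxidative phosphorylation, heat shock chaperones, endoplasmic reticulum stress, antioxidant, apoptosis and p53, cell cycle, inflammatory cytokines, pattern recognition, interferon and antiviral, antigen presentation, complement, circadian clock, glucocorticoid response, immediate early, iron and heme, cholesterol synthesis, ribosomal proteins and proteasome. Marker lists covered B cells, T and NK cells, erythroid cells, granulocytes, macrophages, thrombocytes and endothelium with stroma. Exocrine pancreas, liver and skeletal muscle were included as tissues that a dissection could carry along. Each list was tested against all other genes with camera of limma 3.58.1 (preset correlation 0.01, log CPM with a prior count of 2), with adjustment over the 30 lists, and again with an estimated correlation and with fry, which tests a list without reference to other genes. The rule for named genes took, per comparison, the 6 largest rises and 6 largest falls among significant genes with a mean log2 CPM of at least 2 and no overlap between the groups, up to 3 significant members of each list with the smallest adjusted p, and 12 index genes. Pathways annotated in the table were tested with a hypergeometric test over 9744 tested genes with an annotation, for the 206 pathways with 10 to 500 tested genes.

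Alternatives chosen before the values were seen were DESeq2 1.42.0 size factors, the DESeq2 Wald test, limma on log2(FPKM + 1), other filters on low counts, only the 2 groups compared, a minimum fold change, the replicate number as a block, and each library left out in turn. A further 5 alternatives were chosen after seeing the data: the normoxia and the severe libraries each summed to 1 library, total-count scaling, a correction for transcript length, a fit without globin genes, and the globin share as a covariate. The transcript length was computed from the deposited count and FPKM of each gene, and a smooth trend of each library on it was removed as an offset. To test what the trend alone gave for 3 lists, it was also fitted without their genes with smoothing spans of 0.3, 0.1 and 0.03, and the values printed are from the first.

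The steps were tested on simulated counts with 200 changed genes, in which every group had the spread shared by all 9 libraries. The real groups differed in spread, so the shares called and the false calls may differ for them. At a 2-fold change, 75.7% of changed genes were called for moderate hypoxia against normoxia (27539 genes), 68.5% for severe hypoxia against normoxia (27563 genes) and 66.2% for severe against moderate hypoxia (27652 genes). At a 1.5-fold change the shares were 43.9%, 25.0% and 38.6%. False calls made up 10.1%, 4.00% and 10.9% of all calls. In simulations of 27537 genes with no change and the spread of each group, a mean of 4.40 genes was called for moderate hypoxia against normoxia, 0 for severe hypoxia against normoxia and 4.00 for severe against moderate hypoxia. For a simulated length trend in moderate hypoxia against normoxia over 27527 genes, calls went from 4000 to 1 with the correction. Figures and tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.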

Results

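Spleen transcripts of rainbow trout (Oncorhynchus mykiss), a salmonid farmed in cold and well-oxygenated water, were measured by RNA-seq in 9 libraries that formed 3 groups of 3. Fish of about 130 g were held at 12 °C. The normoxia group was sampled at 0 h from water with 8.5 mg/L of dissolved oxygen, the moderate hypoxia group after 12 h at 4.5 mg/L, and the severe hypoxia group after 12 h at 3.0 mg/L, with each level held within 0.1 mg/L. The comparisons with normoxia therefore differed in both oxygen and time, whereas severe and moderate hypoxia shared their sampling time. Other times and the reoxygenation groups of the study were not analysed here. Of the genes of the table, 28245 passed the expression filter and were tested.

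Globin genes took 16.4% ± 0.28 of all counts in normoxia (SD, n = 3 here and for every mean ± SD that follows), 8.97% ± 3.18 in moderate hypoxia and 9.84% ± 0.07 in severe hypoxia. The 3 moderate libraries differed from each other, with globin shares of 12.3%, 8.70% and 5.93%. Over genes with a summed count of 20 to 1000, the variance between 2 libraries of a group was 1.93 to 2.21 times the Poisson variance in normoxia and 1.98 to 2.33 times in severe hypoxia, against 3.24 to 12.7 times in moderate hypoxia. It was higher for more abundant genes: above a summed count of 10000 it was 3.53 to 22.8 in normoxia, 3.07 to 6.89 in severe hypoxia and 135 to 461 in moderate hypoxia. The biological coefficient of variation was 0.068 in normoxia, 0.219 in moderate hypoxia and 0.061 in severe hypoxia. The labels number the samples of a group but do not say that they came from separate fish, so the p-values measure only the spread between these samples, which may be technical. Transcripts of digestive enzymes of the exocrine pancreas, a tissue that lies beside the spleen, also differed between libraries. Their sum over 26 genes was 2441 ± 19 CPM (counts scaled to library size with TMM) in normoxia, 56.9, 107 and 1860 CPM in the 3 moderate libraries, and 61.4 ± 1.78 CPM in severe hypoxia.

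**Figure D1:**
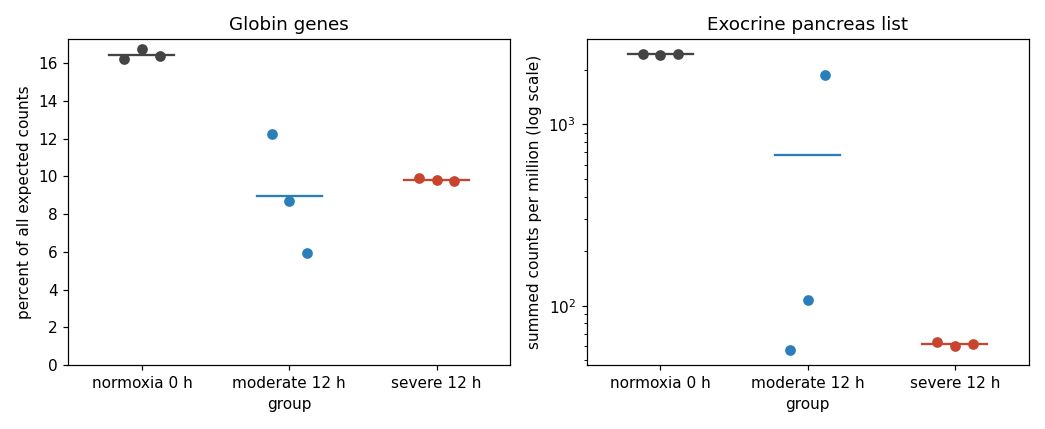
Share of globin genes in the expected counts (left, percent) and summed normalised CPM of the 26 tested exocrine pancreas genes (right, log scale) in each library of the 3 groups; points are libraries and lines are means of 3. The moderate libraries spread from 5.93% to 12.3% globin and from 56.9 to 1860 CPM, and the libraries of each other group lie close together.

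The first comparison asked how the spleen differed after 12 h of moderate hypoxia from normoxia. FKBP5, a co-chaperone of the glucocorticoid receptor (NCBI gene 110494097), had the largest rise among the genes selected by size, from 13.2 ± 0.742 to 105.2 ± 38.4 CPM (log2 fold change 3.00, SE 0.26, adjusted p = 5.55e-05). The clock genes NR1D2 and dbpb, the thrombospondin gene THBS1 and the von Willebrand factor gene vwf rose, while a hemoglobin beta gene, the interferon-related IRF1 and the peroxiredoxin gene PRDX1 fell. PFKFB4, which sets the level of a regulator of glycolysis (110494292), fell from 28.9 ± 1.03 to 6.02 ± 0.986 CPM (log2 fold change -2.26, SE 0.14, adjusted p = 9.22e-08). Epas1, the gene of the oxygen-regulated transcription factor HIF-2α (110499310), rose from 60.5 ± 1.35 to 129 ± 27.4 CPM (log2 fold change 1.09, SE 0.12, adjusted p = 2.01e-05).

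**Figure D2:**
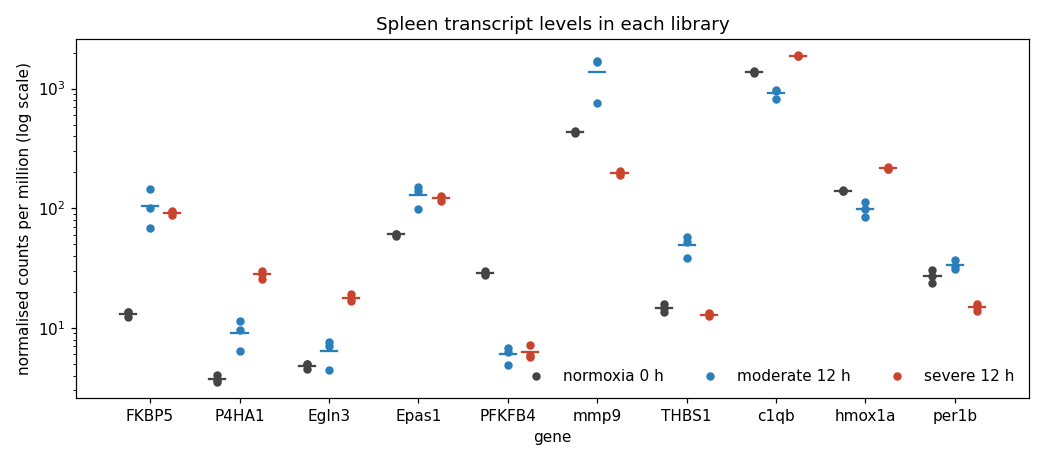
Normalised CPM (log scale) of 10 named genes in the 3 libraries of each group; points are libraries and short lines are means of 3. FKBP5 and Epas1 were higher than normoxia in all 6 hypoxia libraries, P4HA1 and Egln3 were highest in the severe libraries, and mmp9 and THBS1 were highest in the moderate libraries.

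Medians of lists below are of log2 fold changes. Of the 33 tested genes of the glucocorticoid response list, 18 rose and 1 fell, with the same counts when adjusted over the list alone. Their median log2 fold change was 0.54 (camera adjusted p = 0.000353, and adjusted p = 0.0924 with an estimated correlation). Besides FKBP5 they included its second copy fkbp5 (110528325), at 20.6 ± 1.54 and 40.6 ± 9.83 CPM, and foxo1a (110534227), which rose from 13.1 ± 0.698 to 31.6 ± 2.64 CPM. In the circadian clock list 24 of 64 genes rose and 4 fell, also when adjusted over the list alone. Their median log2 fold change was 0.38 (camera adjusted p = 0.00243, and adjusted p = 0.106 with an estimated correlation). NR1D2, a repressor of the clock loop (110515629), rose from 20.7 ± 0.716 to 48.5 ± 3.92 CPM, and dbpb, a clock-controlled transcription factor (110536998), from 16.9 ± 1.37 to 42.7 ± 8.42 CPM. With a correction for transcript length 14 clock genes rose and 5 fell, and the list no longer passed (adjusted p = 0.0889); with total-count scaling 36 rose and 1 fell.

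Marker genes of several spleen cell types moved. Of 19 thrombocyte genes 12 rose and 3 fell, also when adjusted over the list alone. Their median was 0.40 (camera adjusted p = 0.0102, and adjusted p = 0.0924 with an estimated correlation). THBS1, thrombospondin-1 (110505508), went from 14.7 ± 1.03 to 49.6 ± 10.1 CPM, and vwf, von Willebrand factor (110502677), from 23.6 ± 0.579 to 51.6 ± 5.01 CPM. With the length correction 11 thrombocyte genes rose and 2 fell (camera adjusted p = 0.00574, and adjusted p = 0.131 with an estimated correlation). The correction took the log2 fold change of vwf from 1.13 to 0.41 and that of THBS1 from 1.75 to 1.36. The endothelium and stroma list had 20 genes higher and 2 lower of 30, also when adjusted over the list alone. Their median was 0.63 (camera adjusted p = 0.000249, and adjusted p = 0.378 with an estimated correlation). The length correction left 10 higher and 1 lower, at a median of 0.29, and with the globin share as a covariate 4 were higher and 3 lower. They included the smooth muscle genes MYH11 (110485728; log2 fold change 0.92, SE 0.10) and ACTA2 (110498989; 0.60, SE 0.08). Corrected for length, these 2 fold changes were 0.34 and 1.00. Of 42 erythroid genes 26 fell and 1 rose, or 31 and 2 when adjusted over the list alone. Their median was -0.90 (camera adjusted p = 3.30e-08, and adjusted p = 0.381 with an estimated correlation). The length correction left 12 that fell and 1 that rose, at a median of -0.57. One hemoglobin beta gene, hbb (110538444), fell from 3578 ± 83.2 to 1365 ± 199 CPM; 15 genes in the table carry this symbol, so reads could be split between copies. TFRC, the transferrin receptor (100653457), was the erythroid gene that rose (log2 fold change 0.81, SE 0.11). The iron and heme list, which shares 11 of its 32 genes in the table with other lists, had 8 of 26 tested genes lower and 1 higher, also when adjusted over the list alone. Their median was -0.28 (camera adjusted p = 0.0263, and adjusted p = 0.209 with an estimated correlation). With total-count scaling 4 were lower and 5 higher. The iron and heme list missed the threshold without normoxia replicate 1 (0.0503) or moderate replicate 3 (0.0696).

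Of 32 inflammatory genes 15 rose and 1 fell, also when adjusted over the list alone. Their median was 0.34 (camera adjusted p = 0.0244, and adjusted p = 0.260 with an estimated correlation). The call was lost without normoxia replicate 1 (0.0955), moderate replicate 1 (0.216), moderate replicate 2 (0.0553), severe replicate 1 (0.0613) or the globin genes (0.0573). The risen genes included Socs3, a feedback inhibitor of cytokine signalling (110502743; log2 fold change 1.07, SE 0.10), and Tnfaip3, an inhibitor of NF-κB signalling (110502983; 0.80, SE 0.09). The fallen one, COX2 (807980), is the mitochondrial cytochrome oxidase gene that shares its symbol with a cyclooxygenase. In the interferon and antiviral list 19 of 43 genes fell and 0 rose, also when adjusted over the list alone. Their median was -0.36 (camera adjusted p = 6.35e-05, and adjusted p = 0.0628 with an estimated correlation). With total-count scaling 9 fell and 1 rose. IRF1, an interferon-induced transcription factor (110533376), fell from 315 ± 3.19 to 172 ± 15.9 CPM. Antioxidant genes fell in 24 of 44 cases and rose in 0, also when adjusted over the list alone. Their median was -0.49 (camera adjusted p = 5.77e-06, and adjusted p = 0.141 with an estimated correlation). Corrected for length, 9 fell and 2 rose, at a median of -0.20. PRDX1, a peroxiredoxin (110485699), was at 144 ± 2.43 and 74.9 ± 14.7 CPM. In the apoptosis and p53 list 21 of 47 genes fell and 3 rose, or 21 and 4 when adjusted over the list alone. Their median was -0.36 (camera adjusted p = 0.000286, and adjusted p = 0.106 with an estimated correlation). Corrected for length, 11 fell and 4 rose, at a median of -0.11, and with total-count scaling 8 fell and 8 rose, at a median of -0.09. The named members include the survival genes BCL2L1 (110532256; log2 fold change -0.77, SE 0.09) and MCL1 (110487180; -0.59, SE 0.07) and the death gene BAX (110537938; -0.87, SE 0.13).

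The fold changes of moderate hypoxia rose with transcript length. Across 25218 genes the median log2 fold change was -0.53 in the shortest eighth of genes (up to 1365 nt) and 0.61 in the longest eighth (from 5645 nt). The lists with the lowest adjusted p fell among short transcripts. Ribosomal protein genes fell in 151 of 162 cases and rose in 1, also when adjusted over the list alone. Their median was -0.58 (camera adjusted p = 1.37e-32, and adjusted p = 0.106 with an estimated correlation). Of 169 oxidative phosphorylation genes 117 fell and 1 rose, or 122 and 1 when adjusted over the list alone. Their median was -0.54 (camera adjusted p = 3.91e-20, and adjusted p = 0.0634 with an estimated correlation). Of 81 proteasome genes 49 fell and 3 rose, or 52 and 3 when adjusted over the list alone. Their median was -0.39 (camera adjusted p = 3.45e-10, and adjusted p = 0.0924 with an estimated correlation). After the length correction these 3 lists did not pass, with adjusted p of 0.702, 0.411 and 0.393, and 40, 29 and 11 of their genes fell while 34, 9 and 4 rose. With total-count scaling 117, 76 and 24 fell and 2, 5 and 7 rose. Of the antigen presentation genes 14 of 31 fell and 2 rose, or 16 and 2 when adjusted over the list alone. Their median was -0.28 (camera adjusted p = 0.000286, and adjusted p = 0.0634 with an estimated correlation). After the correction this list did not pass either (0.622), with 8 genes lower and 4 higher, the same counts as with total-count scaling. Liver genes fell in 3 of 12 cases, also when adjusted over the list alone. Their median was -0.80 (camera adjusted p = 0.0136, and adjusted p = 0.106 with an estimated correlation; adjusted p = 0.134 after the length correction). Without moderate replicate 3 or moderate replicate 1, 7 and 5 of them fell, and with total-count scaling 1 did.

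**Figure D3:**
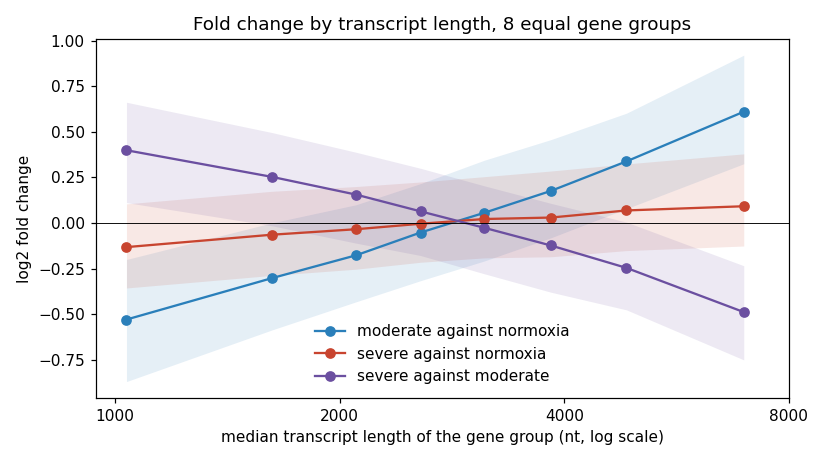
Median log2 fold change (points and lines) and middle 50% of genes (shaded) in 8 equal groups of genes by transcript length (log scale, nt), for the 3 comparisons. The medians run from -0.53 to 0.61 for moderate hypoxia against normoxia, from -0.13 to 0.09 for severe hypoxia against normoxia, and from 0.40 to -0.49 for severe against moderate hypoxia.

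Lists of tissues other than spleen also passed. Skeletal muscle genes fell in 17 of 32 cases and rose in 7, also when adjusted over the list alone. The list test gave a camera adjusted p = 0.0141, and adjusted p = 0.0924 with an estimated correlation. In this list pvalb1, parvalbumin (100500735), was at 4.54 ± 1.37 and 0.166 ± 0.137 CPM. The summed level of the list was not lower, at 581 ± 8.55 and 773 ± 118 CPM, and the test pointed upward among genes with a mean of at least 50 counts (adjusted p = 0.393). Exocrine pancreas genes passed as a list (camera adjusted p = 2.14e-05, and adjusted p = 0.542 with an estimated correlation) with 2 genes lower and 1 higher of 26, also when adjusted over the list alone. Without moderate replicate 3, 25 of these genes were lower. The hypoxia response list did not pass: 13 of its 55 genes rose and 15 fell, or 14 and 16 when adjusted over the list alone (median log2 fold change -0.05, adjusted p = 0.577). With total-count scaling 21 rose and 8 fell, at a median of 0.22. Its risen members included Epas1, hif1a (100135944; log2 fold change 0.54, SE 0.07, adjusted p = 3.76e-05) and the oxygen sensor EGLN2 (110507058; 1.08, SE 0.12), and its fallen members the mitochondrial genes bnip3 (100301704; -1.03, SE 0.09) and Higd1a (110530494; -1.16, SE 0.12). The other 12 lists that did not pass were pattern recognition, glycolysis, endoplasmic reticulum stress, immediate early, granulocyte, macrophage, cell cycle, T and NK cell, heat shock, cholesterol synthesis, B cell and complement genes, with adjusted p from 0.0790 to 0.995. Median, mean and test differed in sign for glycolysis (median log2 fold change 0.30, mean -0.004), B cell, T and NK cell, cholesterol synthesis and immediate early genes. Of these, glycolysis (24 up and 11 down of 52) and endoplasmic reticulum stress genes (15 up and 7 down of 50) passed upward after the length correction, with adjusted p of 0.0101 and 0.0234, but not with an estimated correlation as well (adjusted p = 0.483 and 0.588 with an estimated correlation). Without moderate replicate 3 granulocyte genes passed upward (0.0224), and pattern recognition genes did so without moderate replicate 3 (0.0399) or normoxia replicate 3 (0.0427).

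In all, 11268 genes differed between moderate hypoxia and normoxia, 6002 higher and 5266 lower, of which 2503 changed over 2-fold (1495 up, 1008 down). The libraries of the groups did not overlap for 48.0% of genes. By chance 10% would not overlap if the 6 libraries were independent samples, which the labels do not say. With total-count scaling, which shifted the median log2 fold change by 0.26, 10235 genes were higher and 2664 lower, and limma on log2(FPKM + 1), with a shift of 0.22, gave 8712 and 2893. With the normoxia and the severe libraries each summed to 1 library, 481 genes passed (208 up, 273 down); in that fit normoxia is 1 sample and all spread comes from the moderate libraries. With the length correction 7164 passed (3564 up, 3600 down), 5386 of them with the same direction as without it. The globin share, which itself differed between the groups, left 5636 genes when added as a covariate. Of the lists that passed, clock genes then rose in 8 cases and thrombocyte genes in 5, with 0 lower in either. Erythroid genes rose in 8 and fell in 9, apoptosis and p53 genes fell in 7 and rose in 2, antioxidant genes fell in 12 and rose in 2, and interferon genes fell in 8. Oxidative phosphorylation, proteasome, skeletal muscle, iron and heme and pancreas genes fell in 46, 22, 4, 5 and 25 cases. Ribosomal protein genes fell in 129 and rose in 1, antigen presentation genes fell in 11 and rose in 2, and liver genes fell in 2. Glucocorticoid response genes rose in 14 and fell in 0, and inflammatory genes rose in 13 and fell in 1.

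The second comparison asked how severe hypoxia differed from normoxia. P4HA1, a collagen prolyl hydroxylase of the hypoxia response list (110529637), rose from 3.74 ± 0.232 to 28.03 ± 2.36 CPM (log2 fold change 2.90, SE 0.18, adjusted p = 4.30e-07). Egln3, an oxygen sensor that marks HIF for degradation, rose in both copies, from 4.83 ± 0.269 to 17.9 ± 1.15 CPM in one (110505778; log2 fold change 1.89, SE 0.18) and from 4.59 ± 1.32 to 17.1 ± 1.70 CPM in the other (110497687; 1.88, SE 0.20). The mitotic gene kif11, the T cell gene cd4-1, the complement gene c1qa and the collagen gene col1a2 rose, and the erythroid genes hbb and slc25a37 fell. FKBP5 again stood higher, at 91.5 ± 3.57 CPM (log2 fold change 2.79, SE 0.26, adjusted p = 0.000583).

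Of 55 hypoxia response genes 18 rose and 2 fell, or 21 and 3 when adjusted over the list alone. Their median was 0.21 (camera adjusted p = 0.000739, and adjusted p = 0.0565 with an estimated correlation). Epas1 rose to 122 ± 6.00 CPM (log2 fold change 1.01, SE 0.12, adjusted p = 0.000293), whereas VEGFA (110504679), the vascular growth factor, was at 12.95 ± 1.28 and 11.8 ± 1.38 CPM (adjusted p = 0.555). Glycolysis genes rose in 18 of 52 cases and fell in 7, or 18 and 10 when adjusted over the list alone. Their median was 0.19 (camera adjusted p = 0.00849, and adjusted p = 0.437 with an estimated correlation). Enolase eno1a (100499608) rose from 208 ± 7.59 to 400 ± 4.73 CPM, while PFKFB4 (log2 fold change -2.19, SE 0.14), the lactate dehydrogenase gene ldha (110525514; -0.73, SE 0.15) and an aldolase, ALDOA (110491790; 7.57 ± 0.893 and 0.226 ± 0.0256 CPM), fell. This aldolase fell alongside skeletal muscle genes of similarly low level: pvalb1 (100500735; 4.54 ± 1.37 and 0.212 ± 0.138 CPM), TNNC2 (110492629; 2.19 ± 0.671 and 0.0370 ± 0.0327 CPM) and PGAM2 (110509748; 2.17 ± 0.409 and 0.369 ± 0.0763 CPM).

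Cell cycle genes rose in 24 of 43 cases and fell in 1, or 31 and 1 when adjusted over the list alone. Their median was 0.65 (camera adjusted p = 5.08e-11, and adjusted p = 0.344 with an estimated correlation). The globin share as a covariate left 5 that rose and 1 that fell. The mitotic kinesin kif11 (110529943) rose from 8.75 ± 0.331 to 19.3 ± 1.35 CPM and the mitotic kinase aurkb (110499816) from 5.89 ± 0.673 to 13.5 ± 1.87 CPM. Of 36 T and NK cell genes 17 rose and 0 fell, or 25 and 2 when adjusted over the list alone. Their median was 0.47 (camera adjusted p = 1.50e-07, and adjusted p = 0.344 with an estimated correlation). With the covariate 6 rose and 2 fell. They included cd4-1, the CD4 co-receptor (100136285; log2 fold change 0.62, SE 0.10). Complement genes rose in 10 of 22 cases and fell in 2, or 13 and 2 when adjusted over the list alone. Their median was 0.64 (camera adjusted p = 1.49e-05, and adjusted p = 0.344 with an estimated correlation), and with the covariate 5 rose and 0 fell. The C1q chain c1qa (110510310) rose from 915 ± 7.85 to 1451 ± 5.87 CPM and C4b (110507666) from 96.0 ± 3.67 to 186 ± 2.07 CPM. Macrophage genes rose in 6 of 18 cases and fell in 0, also when adjusted over the list alone. Their median was 0.33 (camera adjusted p = 0.0201, and adjusted p = 0.344 with an estimated correlation). With total-count scaling 9 rose, and with the length correction 4 did. Of the 38 genes of this list 4 belong to other lists as well. The lysosomal protease LGMN (110505985) went from 72.2 ± 2.39 to 132 ± 2.68 CPM. In the endothelium and stroma list 16 of 30 genes rose and 2 fell, or 18 and 2 when adjusted over the list alone. Their median was 0.64 (camera adjusted p = 7.00e-07, and adjusted p = 0.344 with an estimated correlation), and with the covariate 3 rose and 0 fell. Here col1a2, a type I collagen chain (110496633), was at 156 ± 3.67 and 276 ± 4.28 CPM.

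Erythroid genes fell in 16 of 42 cases and rose in 0, or 30 and 0 when adjusted over the list alone. Their median was -0.80 (camera adjusted p = 3.59e-13, and adjusted p = 0.344 with an estimated correlation). Of them 32 fell without moderate replicate 3 and 35 without moderate replicate 1. The hemoglobin gene hbb (110538444) was at 1773 ± 21.2 CPM, and the mitochondrial iron carrier slc25a37 (110536004) had a log2 fold change of -0.95 (SE 0.14). Exocrine pancreas genes fell in 10 of 26 cases and rose in 1, or 25 and 1 when adjusted over the list alone. Together they had a camera adjusted p = 1.16e-14, and adjusted p = 0.344 with an estimated correlation. Without moderate replicate 3 or moderate replicate 1, 25 and 24 of them fell. With the length correction 5 fell and 1 rose. CTRB1, chymotrypsinogen (110515682), fell from 20.6 ± 0.910 to 0.186 ± 0.0112 CPM, and the trypsin gene Prss1 (110503652) stood at 865 ± 11.1 and 5.40 ± 0.338 CPM. The member that rose was a bile salt-activated lipase, MSTRG.28377, at 24.1 ± 0.312 and 41.8 ± 0.576 CPM. Skeletal muscle genes fell in 10 of 32 cases and rose in 1, or 12 and 1 when adjusted over the list alone. As a list they had a camera adjusted p = 0.000103, and adjusted p = 0.0565 with an estimated correlation. Ribosomal protein genes fell in 48 of 162 cases and rose in 7, or 58 and 9 when adjusted over the list alone. Their median was -0.12 (camera adjusted p = 0.000457, and adjusted p = 0.559 with an estimated correlation). With total-count scaling 17 fell and 33 rose, and the list did not pass; with the length correction 12 fell and 40 rose. The test pointed upward after the length correction (adjusted p = 0.174). Proteasome genes fell in 8 of 81 cases, or 7 when adjusted over the list alone. Their median was -0.10 (camera adjusted p = 0.00849, and adjusted p = 0.373 with an estimated correlation; adjusted p = 0.421 after the length correction). With total-count scaling 4 fell and 4 rose, with the length correction 5 fell and 2 rose, and without moderate replicate 1, 14 fell. The median of the list turned positive with total-count scaling. Antioxidant genes fell in 10 of 44 cases and rose in 3, or 16 and 3 when adjusted over the list alone. Their median was -0.13 (camera adjusted p = 0.0397, and adjusted p = 0.508 with an estimated correlation; adjusted p = 0.196 after the length correction). Of these genes 16 fell without moderate replicate 3 and 19 without moderate replicate 1. The list call was lost without normoxia replicate 2 (0.0589), severe replicate 1 (0.0563) or severe replicate 3 (0.0564), and hmox1a, heme oxygenase (110486536), rose against it from 140 ± 0.998 to 215 ± 4.97 CPM. Apoptosis and p53 genes fell in 8 of 47 cases and rose in 2, or 10 and 4 when adjusted over the list alone. Their median was -0.17 (camera adjusted p = 0.00849, and adjusted p = 0.344 with an estimated correlation). With total-count scaling 4 fell and 4 rose, and without moderate replicate 1, 15 fell. Granulocyte genes fell in 4 of 21 and rose in 2, or 9 and 2 when adjusted over the list alone. Their median was -0.32 (camera adjusted p = 0.00849, and adjusted p = 0.522 with an estimated correlation). Of them 12 fell without moderate replicate 3 and 8 without moderate replicate 1.

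Among clock genes 8 of 64 rose and 9 fell, or 9 and 10 when adjusted over the list alone (adjusted p = 0.930), and per1b (100135905) fell from 27.2 ± 3.38 to 14.9 ± 1.12 CPM (log2 fold change -0.87, SE 0.12, adjusted p = 0.000279). The 15 lists that did not pass had adjusted p from 0.0632 to 0.930 and also included the oxidative phosphorylation (0.0632), immediate early (0.0970), glucocorticoid response (0.102), inflammatory (0.621) and interferon lists (0.789). The others were liver (0.138), B cell (0.155), cholesterol synthesis (0.165), thrombocyte (0.497), antigen presentation (0.525), endoplasmic reticulum stress and pattern recognition (both 0.588), heat shock (0.730) and iron and heme genes (0.860). Median, mean and test differed in sign for clock, heat shock and iron and heme genes. Oxidative phosphorylation genes passed downward without normoxia replicate 1 (0.0168) or moderate replicate 1 (0.0386), immediate early genes without the same libraries (0.0492 and 0.0456), and glucocorticoid response genes upward without normoxia replicate 1 (0.0387). EEF1B2 (110538826), an elongation factor gene, showed the largest rise among the genes selected by size, from 1.06 ± 0.317 to 201 ± 9.15 CPM, but the sum of the 2 genes with this symbol was 1190 ± 11.3 CPM in normoxia and 1201 ± 15.3 CPM in severe hypoxia, so the assignment of reads to either copy is uncertain.

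In all, 4547 genes differed between severe hypoxia and normoxia, 2514 higher and 2033 lower, of which 880 changed over 2-fold (586 up, 294 down), and the groups did not overlap for 44.4% of genes. Total-count scaling gave 4060 higher and 1162 lower genes with a median shift of 0.12, and limma on log2(FPKM + 1) gave 3182 and 1085 with a shift of 0.11. The count was 9745 in a fit of these 2 groups alone, without the wider spread of the moderate libraries, 7663 without moderate replicate 1, and 2141 to 2337 without any single normoxia or severe library. With the normoxia and the severe libraries each summed to 1 library, only EEF1B2 passed, with 1056 genes at an unadjusted p under 0.05. With the globin share as a covariate 1291 genes passed. Hypoxia response genes then rose in 15 cases and fell in 2, and glycolysis genes rose in 16 and fell in 3. Erythroid genes rose in 8 and fell in 7, ribosomal protein genes rose in 8 and fell in 8, and antioxidant genes rose in 3 and fell in 3. Pancreas genes fell in 25 cases, proteasome genes in 2, skeletal muscle genes in 1, and apoptosis and granulocyte genes in 0, while 2 macrophage genes rose.

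The third comparison set severe against moderate hypoxia at the same 12 h. The hypoxia response genes P4HA1 and Egln3, the interferon-related gene IFI44 and a copy of the cell cycle gene cdk1 were higher in severe hypoxia, and the clock genes NR1D2 and per1b and the thrombocyte gene THBS1 were lower. The C1q chain c1qb (110510313) was at 915 ± 80.7 CPM in moderate and 1889 ± 16.1 CPM in severe hypoxia (log2 fold change 1.05, SE 0.06, adjusted p = 6.95e-08). The gelatinase mmp9 (100136060), abundant in granulocytes, was at 1387 ± 546 and 198 ± 6.97 CPM (log2 fold change -2.81, SE 0.32, adjusted p = 0.000776).

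Of 55 hypoxia response genes 22 were higher in severe hypoxia and 3 lower, also when adjusted over the list alone. Their median was 0.39 (camera adjusted p = 0.000124, and adjusted p = 0.0403 with an estimated correlation). P4HA1 differed by log2 1.61 (SE 0.17), Egln3 (110505778) by 1.5 (SE 0.17) and the HIF target ankrd37 (110534293) by 1.00 (SE 0.11), whereas Epas1 differed by -0.08 (SE 0.12, adjusted p = 0.672; significant without moderate replicate 1). Interferon and antiviral genes were higher in 15 of 43 cases and lower in 1, also when adjusted over the list alone. Their median was 0.32 (camera adjusted p = 0.000189, and adjusted p = 0.0403 with an estimated correlation). IFI44 (110528445), an interferon-induced gene, was at 4.50 ± 1.62 and 18.2 ± 1.45 CPM. Antigen presentation genes were higher in 13 of 31 cases and lower in 2, or 15 and 2 when adjusted over the list alone. Their median was 0.29 (camera adjusted p = 0.000506, and adjusted p = 0.0499 with an estimated correlation; adjusted p = 0.311 after the length correction). Corrected for length, 6 were higher and 4 lower. Only these 3 of the 20 lists that passed also did so with an estimated correlation. In the comparisons with normoxia no list did. With the length correction as well, the camera adjusted p was 0.046 for hypoxia response, 0.0584 for interferon and 0.578 for antigen presentation genes in severe against moderate hypoxia.

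Cell cycle genes were higher in 24 of 43 cases and lower in 1, or 25 and 1 when adjusted over the list alone. Their median was 0.70 (camera adjusted p = 8.62e-08, and adjusted p = 0.261 with an estimated correlation). One cdk1 gene (110502539), the mitotic cyclin-dependent kinase, was at 2.86 ± 0.816 and 11.9 ± 0.898 CPM. Complement genes were higher in 11 of 22 cases and lower in 2, or 12 and 2 when adjusted over the list alone. Their median was 0.62 (camera adjusted p = 0.000491, and adjusted p = 0.261 with an estimated correlation). T and NK cell genes were higher in 13 of 36 and lower in 3, or 16 and 3 when adjusted over the list alone. The list test gave a camera adjusted p = 0.00436, and adjusted p = 0.316 with an estimated correlation. Macrophage genes were higher in 8 of 18 and lower in 0, also when adjusted over the list alone. Together they had a camera adjusted p = 0.00647, and adjusted p = 0.134 with an estimated correlation. The scavenger receptor marco (110520391) was at 277 ± 40.1 and 451 ± 5.58 CPM. Liver genes were higher in 6 of 12 cases, or 7 and lower in 1 when adjusted over the list alone. Their median was 1.27 (camera adjusted p = 0.00217, and adjusted p = 0.0922 with an estimated correlation). The fibrinogen chain FGG (110534419) was at 6.33 ± 0.939 and 16.6 ± 0.115 CPM, and the whole list summed to 21.5 ± 4.39 and 49.6 ± 1.75 CPM.

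Circadian clock genes were lower in severe hypoxia in 24 of 64 cases and higher in 2, or 25 and 2 when adjusted over the list alone. Their median was -0.35 (camera adjusted p = 0.000491, and adjusted p = 0.0922 with an estimated correlation). NR1D2 was at 48.5 ± 3.92 and 26.3 ± 1.5 CPM and per1b at 33.6 ± 3.04 and 14.9 ± 1.12 CPM. Granulocyte genes were lower in 11 of 21 cases and higher in 1, or 12 and 1 when adjusted over the list alone. Their median was -0.37 (camera adjusted p = 0.00275, and adjusted p = 0.404 with an estimated correlation). Thrombocyte genes were lower in 10 of 19 and higher in 2, or 11 and 4 when adjusted over the list alone. Their median was -0.27 (camera adjusted p = 0.0133, and adjusted p = 0.0941 with an estimated correlation). THBS1 (110505508) was at 49.6 ± 10.1 and 12.9 ± 0.391 CPM. Inflammatory genes were lower in 13 of 32 cases and higher in 2, also when adjusted over the list alone. Their median was -0.31 (camera adjusted p = 0.0133, and adjusted p = 0.259 with an estimated correlation). The list missed the threshold without normoxia replicate 1 (0.0508) or moderate replicate 1 (0.0823). Il1b, interleukin-1β (110509557), went the other way, from 9.95 ± 1.11 to 20.3 ± 1.77 CPM. Glucocorticoid response genes were lower in 12 of 33 cases and higher in 1, also when adjusted over the list alone. As a list they had a camera adjusted p = 0.00883, and adjusted p = 0.15 with an estimated correlation; adjusted p = 0.0538 after the length correction. Pattern recognition genes were lower in 13 of 47 and higher in 1, also when adjusted over the list alone. The list test gave a camera adjusted p = 0.00699, and adjusted p = 0.0922 with an estimated correlation; adjusted p = 0.102 after the length correction. With total-count scaling 22 were lower and 1 higher.

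The short-transcript lists were higher in severe than in moderate hypoxia. Ribosomal protein genes were higher in 149 of 162 cases and lower in 1, or 150 and 1 when adjusted over the list alone. Their median was 0.52 (camera adjusted p = 1.72e-30, and adjusted p = 0.122 with an estimated correlation; adjusted p = 0.0446 after the length correction). Oxidative phosphorylation genes were higher in 114 of 169, and 9 more when adjusted over the list alone. Their median was 0.45 (camera adjusted p = 1.58e-19, and adjusted p = 0.0511 with an estimated correlation; adjusted p = 0.0294 after the length correction). With the length correction 40 ribosomal protein genes were higher and 13 lower, and 21 oxidative phosphorylation genes higher and 2 lower. With both the length correction and an estimated correlation, adjusted p was 0.331 for ribosomal protein and 0.069 for oxidative phosphorylation genes. Proteasome genes were higher in 44 of 81 and lower in 3, or 48 and 3 when adjusted over the list alone. Together they had a camera adjusted p = 2.25e-07, and adjusted p = 0.0941 with an estimated correlation; adjusted p = 0.682 after the length correction. Corrected for length, 5 were higher and 6 lower, and with total-count scaling 23 and 4. Antioxidant genes, higher in 18 of 44 and lower in 3 (19 and 3 when adjusted over the list alone, 6 and 4 with the length correction), also passed. As a list they had a camera adjusted p = 0.00148, and adjusted p = 0.261 with an estimated correlation; adjusted p = 0.311 after the length correction. Apoptosis and p53 genes, higher in 11 of 47 and lower in 4, also when adjusted over the list alone, had a camera adjusted p of 0.0275, and adjusted p = 0.261 with an estimated correlation. With the length correction 4 were higher and 2 lower, and with total-count scaling 5 were higher and 6 lower. The call was lost in both (0.682 with the length correction) and without moderate replicate 2 (0.0627) or moderate replicate 3 (0.0923). Exocrine pancreas genes were lower as a list (camera adjusted p = 0.00148, and adjusted p = 0.592 with an estimated correlation) with 1 gene higher and 1 lower, and 0 of either when adjusted over the list alone. Without moderate replicate 3, 8 of these genes were lower, and without moderate replicate 1, 13 were.

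The 10 lists that did not pass, with adjusted p from 0.0522 to 0.871, were iron and heme, cholesterol synthesis, glycolysis, erythroid, heat shock, B cell, endoplasmic reticulum stress, endothelium and stroma, skeletal muscle and immediate early genes. The skeletal muscle median was -0.02 and the mean 0.05. Without moderate replicate 1 erythroid genes passed (0.000293), and iron and heme genes passed without normoxia replicate 3 (0.0493), moderate replicate 1 (0.0171) or moderate replicate 2 (0.0336). In all, 9474 genes differed, 4614 higher and 4860 lower in severe hypoxia, of which 1564 changed over 2-fold (712 up, 852 down), and the groups did not overlap for 44.9% of genes. Total-count scaling gave 2887 higher and 6975 lower genes with a median shift of -0.14, and limma on log2(FPKM + 1) gave 3077 and 6094 with a shift of -0.12. With the normoxia and the severe libraries each summed to 1 library 7 genes passed, and 4988 had an unadjusted p under 0.05; with the length correction 5741 passed, 4539 of them with the same direction as without it.

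**Figure D4:**
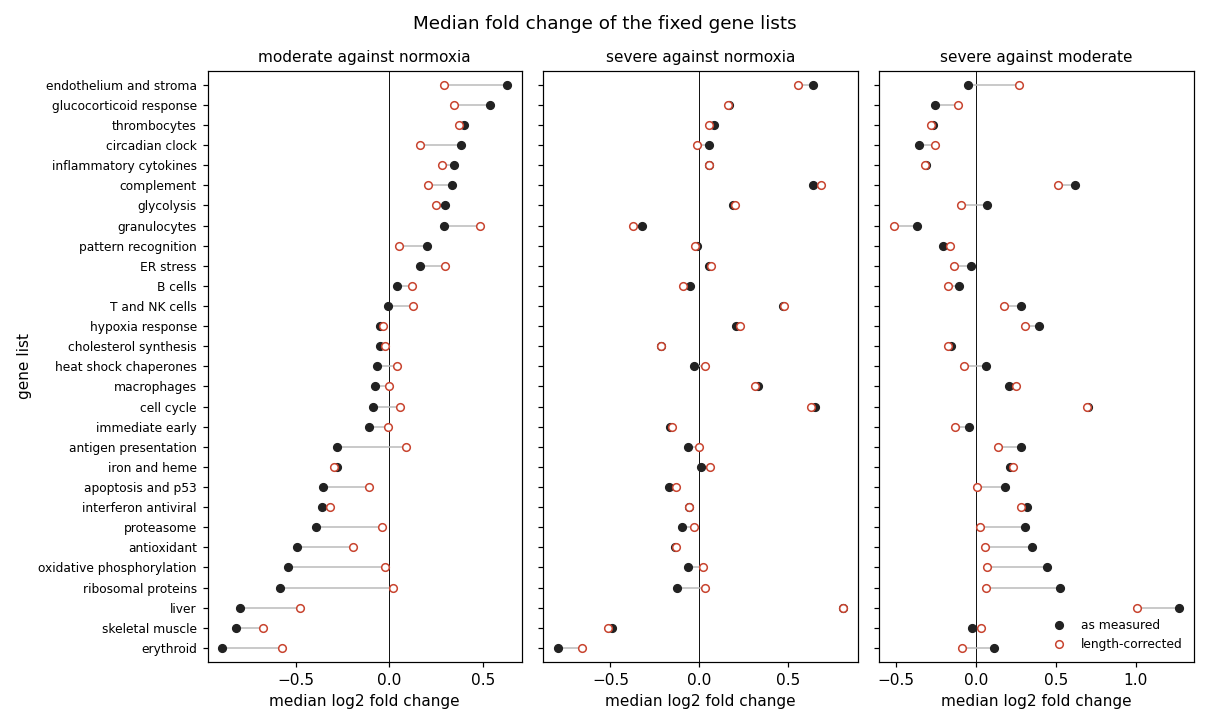
Median log2 fold change of 29 fixed gene lists in the 3 comparisons, as measured (filled points) and after the correction for transcript length (open points); the exocrine pancreas list lies outside the range drawn and is left out. The ribosomal protein, oxidative phosphorylation and proteasome lists lie between -0.58 and -0.39 in moderate hypoxia against normoxia as measured and close to 0 after the correction, and the erythroid list lies at -0.90 as measured in that comparison.

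The moderate and severe responses against normoxia overlapped. In both, 1340 genes were higher and 1236 lower, where independent lists would share 534 and 379. In 20 simulations all 9 libraries were redrawn without any change, with 1 control group for both comparisons, and at most 1 call was shared. That bound says little, since unchanged groups gave almost no calls in either comparison. The log2 fold changes correlated across genes at 0.494, against 0.512 in the simulations. Their covariance was 0.1996, against 0.0425 in the simulations, a difference of 0.157. The simulations gave every group the spread shared by all 9 libraries (biological coefficient of variation 0.137). The measured one was 0.068 in normoxia, 0.219 in moderate and 0.061 in severe hypoxia. The simulated correlation and covariance therefore do not show what shared controls would give at the measured spread. The 3 control libraries could not be split into sets of at least 2, so part of the overlap may come from the shared controls. Both hypoxia groups were also sampled at 12 h and the controls at 0 h, so shared genes may follow time instead of oxygen. The shared count was 2049 after the length correction, 4135 when each pair of groups was fitted alone, and 4771 without moderate replicate 1. It was 1193 to 1333 without any single normoxia or severe library and 0 when those libraries were summed.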

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

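The comparison of 298 genes that moved in opposite directions was made after the counts were seen. Against normoxia, 142 genes rose in moderate and fell in severe hypoxia and 156 fell in moderate and rose in severe hypoxia, together 298 genes (edgeR quasi-likelihood tests, adjusted p under 0.05). Independent lists would share 901 genes in opposite directions. After the length correction 166 genes met the same rule, 93 of them among the 298. The 2 tryptase genes Tpsb2 (110539102), at 4.67 ± 0.539, 0.618 ± 0.333 and 10.6 ± 0.621 CPM in normoxia, moderate and severe hypoxia (SD, n = 3), and TPSAB1 (110539101), at 4.38 ± 0.325, 0.967 ± 0.700 and 9.25 ± 1.11 CPM, met it in both fits, as did c1qb (110510313), at 1376 ± 19.9, 915 ± 80.7 and 1889 ± 16.1 CPM. So did IFI44 (110528445), cdk1 (110502539) and NCOA4, the receptor that takes ferritin to lysosomes (110502354; 241 ± 3.04, 195 ± 15.4 and 291 ± 2.48 CPM), whereas c1qa, hmox1a and per1b did so only without the correction.

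For each comparison, all 10 splits of its 6 libraries into groups of 3 were fitted in the same way, as fixed before the values were seen. The real split was the only 1 of the 10 with as many genes as it gave itself (9547, 9745 and 8071 in these fits of 2 groups), and every other split gave 0. With 10 splits the share cannot fall below 0.1.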

How the results depend on the processing

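Of 22 alternatives, 4, 11 and 3 lay outside 1.5 times of 11268, 4547 and 9474 genes for moderate against normoxia, severe against normoxia and severe against moderate hypoxia, and for the shared genes 9 of 20 did. The normoxia and severe libraries each summed to 1 gave 481, 1 and 7 genes and 0 shared by both responses. The globin share as a covariate gave 5636, 1291 and 11302 genes, the length correction 7164, 4458 and 5741, and an absolute log2 fold change above 1 left 2503, 880 and 1564. Only the 2 groups compared gave 9745 genes for severe against normoxia and 4135 shared genes instead of 2576. With 1 library left out, the counts were 8950 to 13280, 2141 to 7663 and 7169 to 10936, and the shared genes 1193 to 4771; the lowest of the second count and of the shared genes came without normoxia replicate 2 and the highest without moderate replicate 1. The DESeq2 Wald test gave 10997, 4814 and 9309 genes.

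With fry, 28, 23 and 27 of 30 list calls stayed the same, 1, 3 and 1 were lost and 1, 4 and 2 gained. Pancreas genes were lost in moderate against normoxia and severe against moderate (fry adjusted p = 0.0693 and 0.18). Ribosomal protein, antioxidant and granulocyte genes were lost in severe against normoxia (0.0958, 0.0649 and 0.141). With an estimated correlation, interferon, antigen presentation, skeletal muscle, thrombocyte and liver genes lost the camera call in moderate against normoxia. Their estimated correlations were -0.00769, -0.00379, -0.0143, -0.0452 and 0.00963, all below the preset 0.01. The unadjusted camera p of interferon genes went from 1.48e-05 to 0.00209. These losses therefore did not come from a higher correlation between genes. Of 17, 15 and 20 lists that passed with camera, 0, 0 and 3 did so with an estimated correlation. With the length correction 11, 12 and 14 of them kept the call, and glycolysis and endoplasmic reticulum stress in the first comparison and iron and heme genes in the third were gained, though not with an estimated correlation as well (adjusted p = 0.483, 0.588 and 0.259). With 1 library left out 15 to 18, 14 to 18 and 19 to 21 lists passed. The test turned upward for skeletal muscle in moderate against normoxia at a mean of at least 50 counts (adjusted p = 0.393) and for ribosomal proteins in severe against normoxia with the length correction (0.174). With the length correction the log2 fold change changed sign in moderate against normoxia for COX2 807980 (0.06), VEGFA 110504679 (-0.42, adjusted p = 0.0472) and per1b 100135905 (-0.17), and in severe against moderate for MSTRG.28377 (-0.10), hbb 110538444 (-0.07) and COX2 807980 (-0.12). Pathways that passed went from 42 to 12 in moderate against normoxia, from 13 to 15 in severe against normoxia and from 33 to 4 in severe against moderate hypoxia. Those that passed both ways were fewer: 4 risen and 5 fallen, 8 and 1, and 2 and 0. In severe against normoxia the ribosome pathway was enriched among fallen genes before the correction (hypergeometric adjusted p = 2.06e-15) and among risen genes after it (0.000171).

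Libraries with the same replicate number did not resemble each other (correlation of residuals -0.049 to 0.018 over 9 pairs, 1 of 9 libraries closest to its own number). With the number as a block 10852, 4181 and 9085 genes and 17, 14 and 21 lists passed, with 2389 shared genes. An effect of GC content was not tested.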

Other observations

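All tests of explanations in this part, and the choice of the patterns, came after the results were seen. Both copies of NR4A3, an orphan nuclear receptor induced early by many stimuli, rose in both hypoxia groups: nr4a3 (110508134) stood at 0.694 ± 0.113, 3.92 ± 1.11 and 4.08 ± 1.24 CPM in normoxia, moderate and severe hypoxia (SD, n = 3), and Nr4a3 (110534158) at 0.627 ± 0.361, 3.80 ± 0.505 and 3.18 ± 0.134 CPM. The immediate early list as a whole did not pass in any comparison (adjusted p = 0.333, 0.0970 and 0.871). PDE8A, a cAMP phosphodiesterase (110515667), rose from 1.91 ± 0.465 to 11.4 ± 0.162 CPM in moderate hypoxia and stood at 8.29 ± 1.23 CPM in severe hypoxia. The B cell transcription factor gene pax-5 (100136721) rose from 5.53 ± 0.625 to 25.3 ± 3.39 CPM in moderate hypoxia and stood at 6.08 ± 0.293 CPM in severe hypoxia, while the B cell list did not pass in any comparison (adjusted p = 0.798, 0.155 and 0.553). CD79A, a chain of the B cell receptor complex (110537828), fell in severe hypoxia from 349 ± 10.5 to 217 ± 4.64 CPM.

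Heat shock chaperones did not pass as a list (adjusted p = 0.777, 0.730 and 0.553), and the most abundant hsp70 gene (110485160) was at 18.6 ± 1.77, 16.1 ± 3.92 and 18.9 ± 2.11 CPM in normoxia, moderate and severe hypoxia. Another gene with this symbol (110512845) was at 13.2 ± 2.83, 6.17 ± 1.36 and 12.7 ± 1.99 CPM. It fell in moderate hypoxia (log2 fold change -1.10, SE 0.19, adjusted p = 0.000378). The collagen chaperone hsp47 (100135844) rose from 7.52 ± 0.480 to 16.02 ± 3.47 CPM in moderate and 14.5 ± 0.369 CPM in severe hypoxia. Cholesterol synthesis genes did not pass either (adjusted p = 0.795, 0.165 and 0.125). In the endoplasmic reticulum stress list (adjusted p = 0.326, 0.588 and 0.553) the pro-death factor gene DDIT3 (110527691) fell in moderate hypoxia from 37.2 ± 2.78 to 18.9 ± 3.9 CPM.

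Among annotated pathways, ECM-receptor interaction was enriched among risen genes in moderate (79 of 134 genes, hypergeometric adjusted p = 6.12e-20; 1.51e-07 after the length correction) and in severe hypoxia (55 of 134, 5.25e-20; 7.69e-14). Lysosome genes were enriched among risen genes in severe hypoxia (50 genes, 8.92e-06; 0.00103) and among genes higher in severe than in moderate hypoxia (80 genes, 4.61e-06; 0.000320). Necroptosis genes were enriched among those that fell in moderate hypoxia (93 of 263, hypergeometric adjusted p = 1.63e-06), as were porphyrin metabolism genes (20 of 48, 0.0133). After the length correction 58 and 16 of these genes fell (hypergeometric adjusted p = 0.00237 and 0.00867). Of all tested genes with an annotation, 20.9% fell before the correction. The hypergeometric test treats genes as independent, which gene copies and genes that vary together are not.

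The fall of ribosomal protein, oxidative phosphorylation and proteasome genes in moderate hypoxia may come from a trend with transcript length. A trend fitted without these 3 lists left medians of 0.009, -0.04 and -0.039 of their log2 differences of -0.593, -0.541 and -0.4. A few genes taking up more of the counts would not give it. The 10 most abundant genes held at most 10.1% in a moderate library and at least 13.13% in a normoxia library. A response that grows as oxygen falls would not by itself make the lists higher in severe than in moderate hypoxia, as they were (lowest median 0.309). This cannot exclude such a response, since most of that difference followed length. The trend predicted medians of 0.445, 0.423 and 0.296 there, beside measured medians of 0.524, 0.445 and 0.311. In severe against moderate hypoxia the same fit left 0.095 and 0.086 for ribosomal protein and oxidative phosphorylation genes (camera adjusted p = 0.00494 and 0.00803), but with an estimated correlation after the length correction neither list passed (0.331 and 0.069), so whether a part there is not from length stays open. Whether the trend arose in library preparation, RNA quality or the fish is not given in the sources used here.

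Digestive enzyme transcripts could come from pancreas tissue taken along with the spleen. Within the moderate group, where oxygen and time were shared, 92.3% of the list genes were over 4-fold higher in the library with the highest sum than in that with the lowest, and the sums differed 32.7-fold. A response to oxygen alone would not give such a range. The range rests on moderate replicate 3 (1860 CPM), and the libraries compared were ranked by the sum of these same genes. Moderate replicates 1 and 2, at 56.9 and 107 CPM, lay near the severe mean of 61.4 CPM. Dissection that differed between samples is 1 reading, and an effect of hypoxia on this tissue in some samples is another. Pancreas genes should not be read as a spleen response.

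Whether the libraries of the normoxia and of the severe group are repeat libraries of 1 RNA pool or 1 fish stays open. Their variance relative to Poisson was at most 1.09 times higher at a summed count of 500 to 1000 than at 20 to 100, against 2.03 to 2.97 times in moderate hypoxia, but above 10000 it rose to as much as 22.8 in normoxia and 6.89 in severe hypoxia. At most 5 genes with 5 CPM or more differed over 4-fold within either group, against 79 in moderate hypoxia. Summed pancreas transcripts ranged 1.01-fold within normoxia and 1.06-fold within severe hypoxia, against 32.68-fold within moderate hypoxia. Separate fish that vary alike in all 3 groups would not give this difference between groups, but this only restates the pattern. Separate fish in the normoxia or the severe group would have to match that closely in pancreas transcripts as well. Fish of closely similar condition remain possible, and with these groups counted as 1 sample each, so that all spread came from the moderate libraries, 481, 1 and 7 genes passed.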
